A study of Mus musculus with 4 samples.

How the data were processed

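Total RNA from brown adipose tissue, in 2 wild-type and 2 Tsku knockout samples, was converted to biotin-labelled target and hybridised to whole-transcript arrays, 1 per sample, per the labels' protocols. The authors deposited 1 table of normalized log2 expression values with 41345 probe sets and a column for each sample. RMA, oligo and limma are named in the submitters' processing notes without roles, and no version or genome build is given in the sources used here. RMA (robust multi-array average) corrects background, quantile-normalizes arrays and summarises the probes of a probe set. The base of the logarithm is taken as 2 because RMA gives log2 values, and the deposited log2 values, with medians of 0.56 to 0.58 and a lowest value of -1.12, sit below the usual range of RMA by an offset of unstated origin. Differences between arrays do not depend on a constant offset, but each level printed does. Background correction and summarisation pull dim probe sets together, so changes of dim genes are understated. Between 10.7% and 11.1% of the probe sets of an array shared their value with another probe set, up to 590 of them at 1 value, and 1404 probe sets had the same values as another on all 4 arrays. No gene tested had the same 4 values as another.

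Probe sets were named from the platform annotation, in which 23521 had 1 gene symbol, 1814 had several and 16010 had none listed. Of the first, 23328 matched the reference gene table (GRCm38.p6) by Entrez ID, and 0 symbols needed an update. Probe sets with several symbols or none were left out of the gene comparison. For each gene the probe set with the highest mean over the 4 arrays was kept, which gave 22180 genes, 1082 of them with more than 1 probe set. Tsku and Adrb3 had no listed probe set.

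Knockout was compared with wild type in limma 3.58.1 (R 4.3.3) with lmFit and eBayes at default settings on the deposited values, two-sided, with no block, no filter on dim genes and Benjamini-Hochberg adjustment over all genes. The residual degrees of freedom were 2 and the prior degrees of freedom 3.96. Gene lists for pathways, complexes and cell types were tested on the same table with camera from limma, two-sided, at a preset correlation of 0.01, adjusted over the 39 lists with at least 5 measured genes. In all 41 lists were fixed with 860 places for genes, of which 87 were not measured. The list that checks sex was not tested. Members were also counted past an adjusted p of 0.05 over all genes and over the list alone. The threshold throughout was an adjusted p under 0.05.

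The genes named are Tsku, a panel of Ucp1, Dio2, Ppargc1a, Cidea, Th, Adrb3, Adipoq and Lep, and up to 10 genes in each direction with the largest change among those past the threshold whose arrays do not overlap between genotypes. Where fewer than 10 passed, the places went to the smallest unadjusted p among genes with an unadjusted p under 0.01 and an absolute log2 change of at least 0.58, and such genes are said not to have passed. Predicted genes, microRNA genes, small nucleolar RNA genes and olfactory or vomeronasal receptor genes were skipped. Up to 4 members with the smallest unadjusted p, and members that passed, were named for each list described. Outside this rule stand the genes that check sex and the genes of the extra tests in the closing section, and Myh4, Tcap, Txlnb, Srl, Jph1, Alb, Apoa2, Fgb, Tat, Apob, Fga and Fgg were chosen after their values were seen. The test, the gene lists, the naming rule and all alternatives but 1 were fixed before the data were examined.

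Background was defined after the data were seen as the 95th percentile, on each array, of 1405 probe sets for olfactory and vomeronasal receptors, genes that brown fat is not known to use. Where both arrays of a genotype lay at or below it, the fold is a lower bound: the brighter genotype's mean log2 value against the mean, per array, of the higher of that percentile and the dim probe set's own value. The scripts were tested on simulated data built from the same 22180 genes. The test called 38 of 50 genes planted with a log2 change of 2 and 48 of 50 with 3. It called 0 of 50 with 1, 0 of 50 with 0.58 and 4 unchanged genes. Camera called both lists planted with a shift of 0.6 and 0 others. The noise was drawn independently for each gene, so the simulation cannot show how often lists of correlated genes are called falsely. The many planted genes also ease the adjustment, so the recovery does not carry over to data with few changed genes.

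Alternatives covered a replicate block, filters on dim genes at the median and lower quartile, the mean or most variable probe set of a gene, repeated quantile normalization, median centring and cyclic loess, a mean trend, robust and unmoderated variances, array weights, other thresholds, every probe set, and each sample left out in turn. For lists they also covered an estimated correlation, ranks and fry, which tests whether the members of a list move one way on balance without comparing them with other genes. The cell composition of the samples, the feeding state and the dissection are not given in the sources used here.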

Results

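Gene expression was profiled in brown adipose tissue, the fat depot that burns fuel to make heat, from male C57BL/6 mice aged 4 months and kept on chow. The labels give 2 wild-type samples and 2 samples from mice lacking Tsku, which encodes tsukushi, a secreted member of the small leucine-rich proteoglycan family. Each sample has 1 whole-transcript array, and each array has a log2 expression value for 41345 probe sets. Array medians lay between 0.56 and 0.58, and the highest values between 11.56 and 11.78. Between 50.2% and 53.6% of the 22180 genes tested lay above the background on an array, taken as the 95th percentile of 1405 olfactory and vomeronasal receptor probe sets. The number of arrays limits the precision, and the median half-width of the 95% interval of a log2 change was 0.52.

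The labels call the 2 samples of each genotype biological replicates, and nothing further says that they came from separate mice, so the p-values measure only the spread between these samples, which may be technical. Across genes, which are not independent replicates, Pearson's r was 0.983 between the wild-type arrays and 0.981 between the knockout arrays. The highest value, 0.985, was between wild-type replicate 1 and knockout replicate 2, and the lowest, 0.977, between wild-type replicate 2 and knockout replicate 1. The spread between arrays of 1 genotype was therefore about as large as the spread between genotypes.

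The comparison of knockout with wild type asks what the loss of Tsku does to the brown fat transcriptome. Tsku itself had 0 listed probe sets, so the deletion could not be checked in these arrays and the genotypes rest on the labels alone. The Y-linked genes Eif2s3y, Kdm5d and Uty were above background on all 4 arrays, and Xist, the RNA that silences an X chromosome in females, was below it on all 4.

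The difference with the smallest p was in Cyp2b10, a cytochrome P450 that metabolises drugs and steroids. It measured 0.74 ± 0.18 (SD, n = 2) in wild type and 4.39 ± 0.23 (SD, n = 2) in the knockout, a log2 difference of 3.65 (SE 0.21, 95% interval 3.12 to 4.17) or 12.5-fold. In wild type 1 of its 2 arrays was above background. None of its 4 measured paralogs was above background on all arrays. In the same samples 20 liver genes had a median log2 change of 0.31, the largest being 1.81 for Alb. Against the wild-type mean that median was 0.55 in knockout replicate 1 and 0.11 in knockout replicate 2. Alb read 5.77 and 4.41 in the knockout, against 3.68 and 2.87 in wild type. Dio2, the deiodinase that makes active thyroid hormone inside brown fat, had a log2 difference of 2.03 (SE 0.23) or 4.08-fold, and Tshr, the thyrotropin receptor, one of 1.70 (SE 0.22) or 3.25-fold. Fabp3, a fatty acid binding protein, differed by 1.37, but by 0.55 with the mean of all its probe sets. Gys2, a glycogen synthase, differed by 1.53 and Pmvk, an enzyme of the cholesterol pathway, by 1.19. Mmd2 differed by 1.55, Mill2 by 1.44 and the small heat shock protein gene Hspb8 by 1.32. Ugt3a2, a glycosyltransferase gene, was below background in wild type and at least 1.29-fold higher in the knockout.

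Several of the genes with lower values in the knockout are known from striated muscle. Tnni2, a fast troponin, had a log2 difference of -2.25 (SE 0.24), its partner Tnnc2 one of -1.82 (SE 0.29), and Cox6a2, the muscle form of a cytochrome oxidase subunit, one of -2.18 (SE 0.34). A further 3 muscle genes were below background on both knockout arrays. Their wild-type signal was at least 9.66-fold higher for Myot, at least 2.21-fold for Abra and at least 2.10-fold for Klhl31. These bounds are of means, and Myot read 3.38 and 4.68 on the wild-type arrays. Cish, an inhibitor of cytokine signalling, differed by -2.11, with 1 of 2 knockout arrays above background, and by -1.19 with the mean of all its probe sets. Klf2, a transcription factor prominent in endothelium, differed by -1.68. Chil3, a product of alternatively activated macrophages, was below background in the knockout and at least 2.00-fold higher in wild type, and Acot9, an acyl-CoA thioesterase, differed by -1.09.

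None of these genes passed the threshold: with limma and Benjamini-Hochberg adjustment, 0 of 22180 genes had an adjusted p under 0.05. Cyp2b10 came closest (adjusted p = 0.0624), and the next smallest adjusted p was 0.736. At an unadjusted p under 0.05 there were 1234 genes, 642 higher and 592 lower in the knockout, where 1109 would be expected with no effect; the balance turned to 416 higher and 713 lower without wild-type replicate 2 and was 596 and 358 without knockout replicate 1. The 2 genotypes did not overlap in 7814 genes (35.2%), where chance gives 33.3%. In simulated data of the same size this test recovered 0% of genes planted with a log2 change of 1. It recovered 76% of those with 2 and 96% of those with 3. Each planted change was given to 50 genes, and many passing genes ease the adjustment for the rest. In the real data, with 0 genes past the threshold, Dio2 at 2.03 and Myot at -3.39 had a limma adjusted p of 0.736. Cyp2b10 passed with replicate number as a block (adjusted p = 0.0251), with arrays centred on their medians (0.0499), with a mean trend in the prior variance (0.0194), without wild-type replicate 1 (0.00518) and without wild-type replicate 2 (0.0185). Over all its alternatives the limma adjusted p ran from 0.00518 to 0.927, and the count of genes past the threshold was 15 without wild-type replicate 1 and 2 without wild-type replicate 2.

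**Figure D1:**
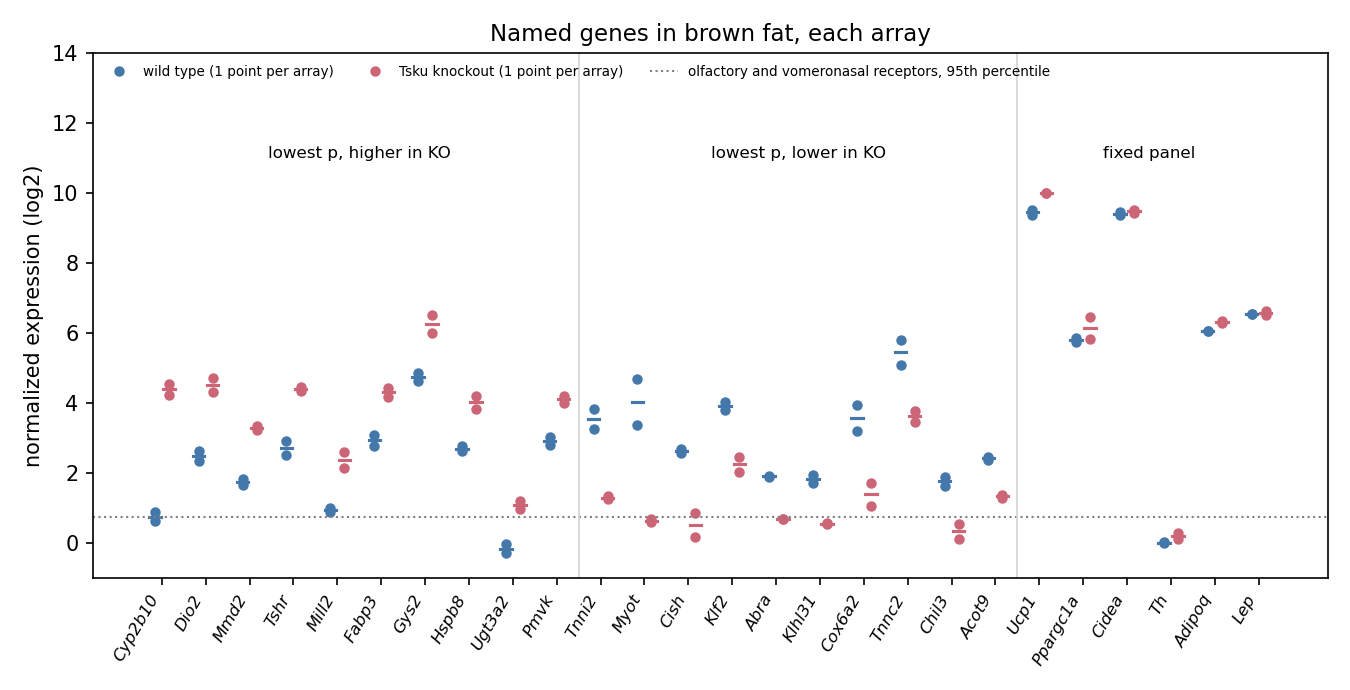
Normalized log2 expression of the named genes on each array (points) with the mean of each genotype (bars), for wild type (blue) and Tsku knockout (red). The dotted line is the mean over arrays of the receptor background; Cyp2b10 averaged 0.74 in wild type and 4.39 in the knockout, and Th stayed below the line on all 4 arrays.

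The fixed panel of brown fat genes gave smaller differences than Dio2. Ucp1, the uncoupling protein that makes heat in brown fat mitochondria, measured 9.45 ± 0.11 (SD, n = 2) in wild type and 9.997 ± 0.006 (SD, n = 2) in the knockout, a log2 difference of 0.55 (95% interval 0.10 to 0.997, limma adjusted p = 0.872). Ppargc1a, the coactivator of mitochondrial biogenesis, differed by 0.35 (95% interval -0.29 to 0.98), by 0.03 without knockout replicate 1 and by 0.67 without knockout replicate 2. The lipid droplet gene Cidea differed by 0.07 (-0.37 to 0.52), and by 0.03 to 0.11 without single arrays. The adipokine genes Adipoq and Lep differed by 0.25 (-0.19 to 0.69) and 0.03 (-0.42 to 0.47), the latter turning to -0.03 without knockout replicate 1. Th, the rate-limiting enzyme of catecholamine synthesis in sympathetic nerves, was below background on all 4 arrays. Adrb3 had no listed probe set and was not analysed here.

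Of 39 gene lists tested with camera, 6 passed the threshold at the preset correlation of 0.01, 2 higher and 4 lower in the knockout. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.910. That setting rests on the 2 residual degrees of freedom, so with 4 arrays it has little power to call a list. Skeletal muscle, with all 24 members lower, had an unadjusted camera p of 0.0962 there. The directional fry test called 0 lists, with a smallest adjusted p of 0.482, and camera on ranks called 5.

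Genes of de novo fatty acid and triglyceride synthesis rose as a group. All 21 measured members were higher in the knockout, with a median log2 change of 0.34 (camera adjusted p = 4.48e-09; adjusted p = 0.910 with an estimated correlation). Of these 7 had an unadjusted p under 0.05, 0 passed over all genes and 2 passed adjusted over the list alone. Those were Fasn, the fatty acid synthase (log2 difference 1.67, SE 0.29, limma adjusted p = 0.0269), and Pnpla3, a lipid droplet hydrolase induced with lipogenesis (1.22, SE 0.28, adjusted p = 0.0485). Acss2, which makes acetyl-CoA from acetate, differed by 0.75 and Agpat2, an acyltransferase of triglyceride synthesis, by 0.80. The call held without each array in turn, with medians between 0.26 and 0.38. In the same samples the median change was 0.31 for 20 liver genes chosen outside the fixed lists, 0.13 for 17 abundant adipocyte genes, -1.50 for skeletal muscle genes and -0.38 for macrophage markers.

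Genes of thermogenesis and brown adipocyte identity were also higher as a group. Of 22 measured members 17 were higher, with a median log2 change of 0.33 (camera adjusted p = 0.00243; adjusted p = 0.910 with an estimated correlation). Of these 5 had an unadjusted p under 0.05, 0 passed over all genes, and 3 passed adjusted over the list alone: Dio2, Fabp3 and Otop1, a proton channel gene with a log2 difference of 1.09. The Fabp3 value rests on its brightest probe set (0.55 with the mean of its probe sets). Prdm16, a transcription factor that sets brown fat identity, differed by 0.999. Without knockout replicate 1 the median was 0.16 with the call kept, and without knockout replicate 2 it was 0.13 and the call was lost (adjusted p = 0.0715). In the same samples the 17 abundant adipocyte genes, Cidea among them, had a median change of 0.13, at the 99.9th percentile of random lists matched on expression, the 20 liver genes one of 0.31, skeletal muscle genes one of -1.50 and macrophage markers one of -0.38. The genes that adrenergic or cAMP signals induce in brown fat, among them Dio2 and Ucp1 again, did not pass (14 of 24 higher, median 0.13, adjusted p = 0.689), and 1 of them, Dio2, passed adjusted over the list alone. Without knockout replicate 1 that list passed as higher (median 0.19, adjusted p = 0.0418). The sympathetic neuron markers did not pass (median 0.11, adjusted p = 0.689), and 1 of their 21 measured members was above background, so few nerve transcripts were measurable here.

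The skeletal muscle genes fell as a group and by the most. All 24 were lower in the knockout, with a median log2 change of -1.50 (camera adjusted p = 2.82e-17; adjusted p = 0.910 with an estimated correlation). Of these 15 had an unadjusted p under 0.05, 0 passed over all genes and 10 passed adjusted over the list alone, among them Tnni2, Tnnc2, the actin gene Acta1 (-1.90) and the calcium buffer Pvalb (-2.25). Levels also differed within a genotype. Set against each gene's mean over the 4 arrays, the list's median was 0.46 and 1.23 on the wild-type arrays and -0.18 and -1.11 on the knockout arrays. Myh4, a fast myosin, read 5.05 and 5.75 in wild type and 5.74 and 1.57 in the knockout. Without knockout replicate 2 the list's median change was -0.89, and the call held without each array in turn.

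The creatine and calcium cycling genes were lower as a group (9 of 13 lower, median -0.19, camera adjusted p = 0.0315; adjusted p = 0.910 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. The 4 members with an unadjusted p under 0.05 were Ryr1 (-0.58), Ckb (-0.76), Atp2a1 (-1.61) and Ckmt2 (-1.56). Ryr1 and Atp2a1 encode the calcium release channel and calcium pump of skeletal muscle and Ckmt2 its mitochondrial creatine kinase, and in the same samples the skeletal muscle list changed by -1.50 and the macrophage list by -0.38. A step added after the data were seen took out such genes, Ryr1, Atp2a1 and Ckmt2 among them. It thereby removed members with the smallest p, so loss of the call was likely whatever its cause. The list then no longer passed (median -0.09, camera adjusted p = 0.510). Nor did it pass without knockout replicate 1 (median -0.10, adjusted p = 0.338) or wild-type replicate 2 (-0.30, 0.0841), with the filter at the median (-0.34, 0.0949), with the mean (0.0736) or most variable (0.0756) probe set, or on ranks (0.0763), and without knockout replicate 2 the median was -0.32 with the call kept.

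Heat shock and chaperone genes were lower as a group (16 of 19 lower, median -0.20, camera adjusted p = 0.00243; adjusted p = 0.910 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Cryab, a small heat shock protein abundant in muscle, differed by -0.62, Dnajb9, a chaperone of the endoplasmic reticulum, by -0.72, and Hspa1a, an inducible Hsp70 gene, by -1.22. Skeletal muscle genes (median -1.50) and macrophage markers (-0.38) were lower in the same samples. With Cryab taken out as a muscle gene, a step added after the data were seen, the list still passed (median -0.19, camera adjusted p = 0.00940). No other member was removed, so the step does not exclude a share of muscle RNA in the difference. Without knockout replicate 1 the median was -0.12 and the call was lost (adjusted p = 0.251), and without knockout replicate 2 the median was -0.34.

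Macrophage markers were lower as a group (18 of 19 lower, median -0.38, camera adjusted p = 0.000273; adjusted p = 0.910 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The complement gene C1qc differed by -0.85, the lysosomal marker Cd68 by -0.88 and the scavenger receptor Cd163 by -0.57. Skeletal muscle genes had a median change of -1.50 in the same samples. The difference came mainly from knockout replicate 1, where the list's median lay at -0.55 against each gene's mean, while knockout replicate 2 lay at 0.08, between the wild-type values of 0.06 and 0.24. Without knockout replicate 1 the median change was -0.12 and the call was lost (adjusted p = 0.345), and without knockout replicate 2 it was -0.65.

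**Figure D2:**
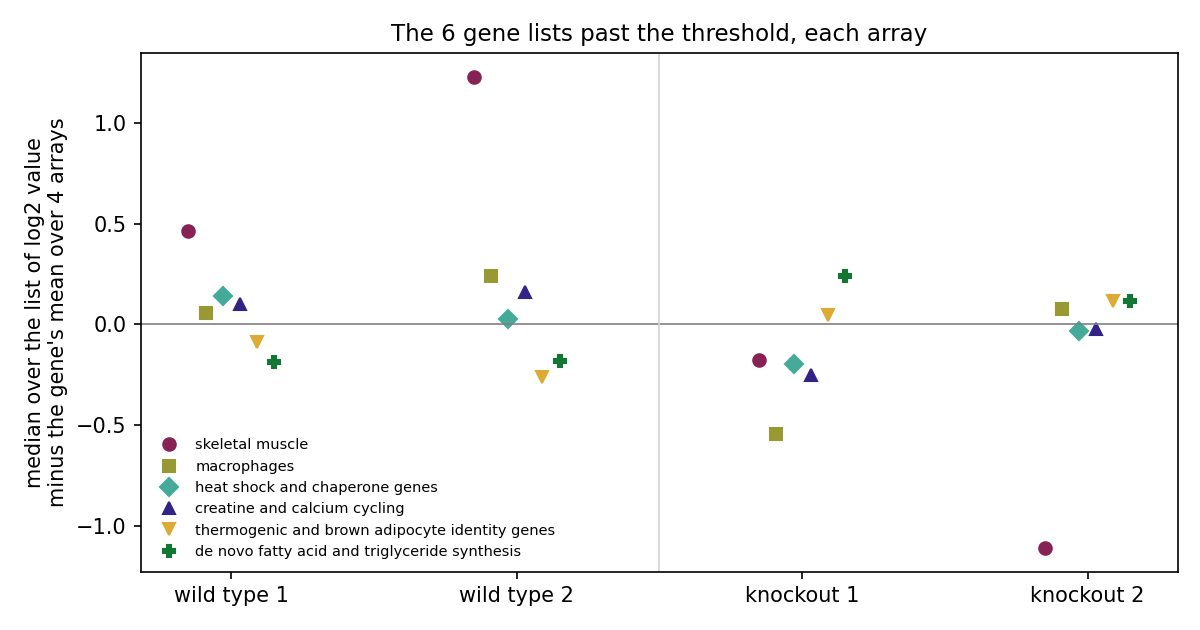
Median over each of the 6 lists of the log2 value minus the gene's mean over the 4 arrays, for each array. The skeletal muscle list runs from 1.23 on wild-type array 2 to -1.11 on knockout array 2, and the macrophage list is low on knockout array 1 alone, at -0.55.

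The other 33 lists did not pass, with camera adjusted p-values from 0.0522 to 0.915. The nearest were inflammatory mediators (median -0.08, adjusted p = 0.0522), cell cycle genes (median -0.14, 0.0601), respiratory chain complexes II to IV with ATP synthase (27 of 34 higher, median 0.08, 0.0759) and cholesterol synthesis (median 0.15, 0.121). Of these 33 lists, 8 passed under at least 1 alternative. The respiratory chain list passed as higher in 3, cell cycle as lower in 3 and inflammatory mediators as lower in 2. Immediate early genes passed as higher without knockout replicate 1 (median 0.52, adjusted p = 0.0263) and as lower without knockout replicate 2 (median -0.39, adjusted p = 5.1e-07). Cholesterol synthesis passed as higher without wild-type replicate 1 (adjusted p = 0.0198), collagens and matrix as lower without wild-type replicate 2 (0.0442) and endothelial genes as higher without knockout replicate 1 (0.0263). Complex I (median 0.04, adjusted p = 0.793) and fatty acid oxidation (median 0.02, 0.689) did not pass. Nor did the small leucine-rich proteoglycans, the family of Tsku (median 0.04, 0.886), or white adipocyte genes (median -0.08, 0.793). Median, mean and test differed in sign for 6 of the lists: adrenergic receptors and catecholamine handling, axon guidance and neurotrophic factors, small leucine-rich proteoglycans, proteasome, smooth muscle cells and pericytes, and T and natural killer cells. Red blood cell genes, with 4 measured, were not tested, and their median was 0.16.

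**Figure D3:**
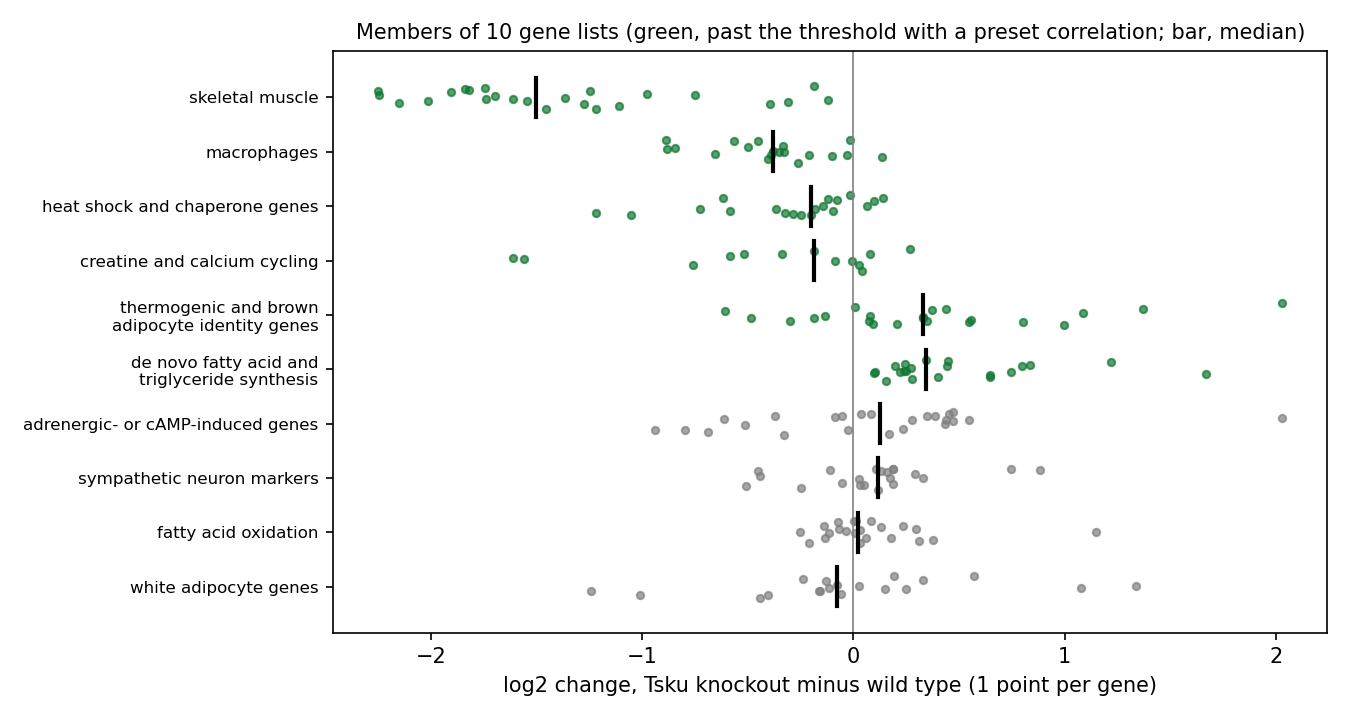
Log2 change (knockout minus wild type) of each measured member (points) and the median (bar) for the 6 lists past the threshold at the preset correlation (green) and 4 that did not pass (grey). All 24 skeletal muscle genes lie below 0 and all 21 lipid synthesis genes above it.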

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

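The tests on abundant adipocyte genes, on muscle genes within a genotype, on liver genes in single knockout samples, on liver genes at background in wild type and on unnamed probe sets were chosen only after the results were seen. The random lists matched on mean expression, used here and in the results, drew genes that need not move together. Members of a cell type list can move together (estimated correlation 0.43 for skeletal muscle). The range of the random lists therefore does not measure the spread between samples, and such a list can leave it without an effect of genotype.

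Some signal lay in the 17824 probe sets with several genes or none listed, which the gene comparison did not use. Of these, 9 were at background on both wild-type arrays and at least 2 log2 units higher on both knockout arrays, and 9 showed the converse. The other 2 splits of the 4 arrays gave 1 and 5, and 3 and 8. Both counts were highest in the real split, but 9 against 8 is close and 3 splits are too few to exclude chance. Against the background of the dim genotype, probe sets 17549080 and 17549054 were at least 5.27-fold and 5.25-fold higher in the knockout. In wild type 17270086 and 17210509 were at least 10.8-fold and 8.59-fold higher. These bounds are of means, and 17210509 read 3.05 and 4.67 on the wild-type arrays. Probe sets 17270086 and 17210509 had identical knockout values of -0.09 and 0.69. Between 10.7% and 11.1% of the probe sets of an array shared their value with another.

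Skeletal muscle genes were lower in the knockout. A second list of muscle genes, 21 measured, 3 of them above background on all arrays and 0 of them in another list, had a median log2 change of -0.35 with 15 lower and 6 higher, below the 2.5th percentile of -0.14 among 10000 random lists matched on mean expression, as less muscle tissue in the knockout samples would give. Of the 3 members above background Txlnb differed by -0.79, but Srl by 0.22 and Jph1 by 0.06, and Tcap, with the largest change, read 1.99 and 3.74 in wild type and 0.85 and 0.36 in the knockout, the last below background. The first list also differed between samples of 1 genotype, by -1.18 from knockout replicate 1 to 2 and by 0.56 from wild-type replicate 1 to 2, both outside matched lists, so carry-over of muscle at dissection may vary whatever the genotype; the second list differed by 0.32 between wild-type arrays, outside matched lists, but by -0.09 between knockout arrays, inside them. A change of muscle-type transcription by the loss of Tsku was not tested and stays open.

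Lipid synthesis genes were higher in the knockout. A larger share of adipocyte RNA would raise abundant adipocyte genes alike. However, 17 such genes outside the list had a mean log2 change of 0.13 against 0.49, a difference of -0.35 (95% bootstrap interval -0.55 to -0.18). The bootstrap drew genes on the same 4 arrays, so its interval does not measure the spread between samples. For these arrays the values argue against a larger share as the whole cause. These 17 genes also stood high, with a median of 0.13 at the 99.9th percentile of matched random lists, so a larger share may account for part (of all 18 measured, 14 also stand in other lists). A more fed state of the knockout mice was tested on 14 fasting-induced genes. Their median of -0.14 stood at the 2.8th percentile of matched random lists, short of the 2.5th set beforehand. Their mean of -0.11 had a bootstrap interval, again over genes, of -0.21 to -0.0006. Several members were lower on knockout array 1 than on knockout array 2, such as Angptl4 (6.79 and 7.83, against 7.76 and 7.60 in wild type). Txnip read 9.09 and 9.71 on the knockout arrays, against 9.65 and 9.68 in wild type. Foxo1 (5.91 and 5.49) and Zbtb16 (4.28 and 3.60) went the other way between the knockout arrays. Feeding state and genotype cannot be told apart here, because the sources give no feeding state and the test fell at its bound, and an effect of the loss of Tsku on lipogenesis stays open as a hypothesis.

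Cyp2b10 was higher in the knockout, and its own signal and that of its paralogs cannot be told apart: the highest upper 95% limit among Cyp2b9, Cyp2b13, Cyp2b19 and Cyp2b23 was 1.09 against a lower limit of 3.12 for Cyp2b10, the bound set beforehand, but 0 of the 4 were above background on all arrays and dim probe sets understate change. Liver RNA as the whole cause was examined in the 10 of 20 liver genes that lay at or below background on both wild-type arrays. Their highest upper 95% limit was 1.93 (Tat), below the lower limit of 3.12 for Cyp2b10. Apob, Fga and Fgg read 1.19, 1.04 and 0.54 on knockout array 1, where the background was 0.81. On knockout array 2 they read 0.002, 0.18 and -0.11. These genes lie near the floor, where dim probe sets understate change, so they cannot decide the question. Liver RNA stays open, as the whole cause or as a part. All 20 genes, 0 of them in the fixed lists, had a median log2 change of 0.31. That lay above the central 95% of matched random lists, which reached 0.17. Of the 7 above background on all arrays Alb, with the largest change, differed by 1.81 (upper 95% limit 3.02). The other 6 differed by 0.09 (Fgb) to 1.17 (Apoa2). Liver RNA in 1 knockout sample or in both cannot be told apart: the median of all 20 was 0.55 in replicate 1 and 0.11, inside the matched range, in replicate 2, and that of the 7 was 1.06 and 0.20, the latter again inside, with 7 of 7 higher in replicate 1 than on both wild-type arrays and 4 of 7 (Alb, Apoa2, Hpx and Vtn) in replicate 2, which are too few to exclude a smaller amount there. An induction of Cyp2b10 in fat by the loss of Tsku was not tested and stays open.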

How the results depend on the processing

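The count of 0 genes past the threshold was 0 under 13 of 20 alternatives. It became 1 with replicate number as a block, 1 with arrays centred on their medians, 1 with a mean trend and 1 at an adjusted p under 0.10, and 227 at an unadjusted p under 0.01 with an absolute log2 change of at least 0.58. It ran from 0 to 15 without single samples (15 without wild-type replicate 1, 2 without wild-type replicate 2). Leaving out a sample leaves a genotype with 1, assumed to vary like the other genotype. The looser thresholds admit more genes by construction, and the cause of the other moves was not tested. Genes at an unadjusted p under 0.05 ran from 713 to 1621. The 6 lists past the threshold became 0 with an estimated correlation and 0 with fry. Both tests allow for members that move together, but this is not their only difference from the preset. The creatine and calcium cycling list had an estimated correlation of -0.004, below the preset 0.01. Its unadjusted camera p still went from 0.00484 to 0.0965. Of the 6 lists, 3 were shared without knockout replicate 1, 5 without knockout replicate 2, 6 without wild-type replicate 1 and 5 without wild-type replicate 2. Without muscle genes, an alternative chosen after seeing the data, 5 lists passed. Of 413 pairs of a named gene and an alternative, 403 kept direction and side of the threshold, 9 newly passed and 1 reversed (Lep, -0.0332 without knockout replicate 1 and 0.0897 without knockout replicate 2, cause not tested). The replicate block left the count of lists at 6. Same-numbered arrays shared only a number: their deviations from group means correlated at -0.0726 across genes. Alternatives for Tsku had no value to give, nor had robust eBayes for lists. Signal over background limits what dim genes such as nerve markers can show, since at most 53.6% of genes lay above it.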

Other observations

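The tests on splits of the arrays were chosen only after the results were seen. Outside the lists that passed, single members passed when adjusted over the list alone, as is each adjusted p of this paragraph. That adjustment does not allow for the number of lists searched, so some members may pass with no effect. Among smooth muscle and pericyte genes, Cspg4 (log2 difference 0.98) and Notch3 (0.95), both pericyte genes, were higher in the knockout, both with a limma adjusted p = 0.0354, while the list's median was -0.06. Among fatty acid oxidation genes, the peroxisomal thiolase Acaa1b differed by 1.15 (adjusted p = 0.0430), and in cholesterol synthesis Pmvk by 1.19 (adjusted p = 0.0163). Lower in the knockout were Klf2 among immediate early genes (-1.68, adjusted p = 0.00616), the interferon-induced gene Ifit3 (-1.44, adjusted p = 0.0250), Nnat among white adipocyte genes (-1.01, adjusted p = 0.0283) and Cd55 among fat progenitor genes (-0.98, adjusted p = 0.0326). None passed over all genes.

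The targeted allele could alter its neighbours, but no such effect was seen. The 20 measured genes nearest to Tsku on chromosome 7, 10 on each side, had a mean absolute moderated t of 0.763. This stood at the 11.2th percentile of 21729 windows of 20 neighbouring genes, and 0 of the 20 had an unadjusted p under 0.05. A mean over 20 genes would dilute a change of a single neighbour. Intervals of single genes were also wide, such as -1.62 to 0.82 for Lrrc32, so a change of single neighbours is not excluded.

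The 4 arrays allow 3 splits into equal groups, too few for a share under 0.05. The real split gave 6 lists past the threshold and the highest of the others gave 4. For genes at an unadjusted p under 0.05 the real split gave 1234 and the highest of the others 1163. As many lists or as many genes came from 1 of the 3 splits, the real one. Skeletal muscle also passed, with a median difference of 0.82, when wild-type replicate 1 and knockout replicate 2 were set against the other arrays, and macrophage markers passed, at 0.36, when first replicates were set against second ones.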
